A study of Mus musculus with 45 samples.

How the data were processed

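RNA from 45 cultures of mouse induced pluripotent stem cells (iPSCs) was measured on expression arrays. Per the labels, cells were grown in medium with serum and LIF on irradiated embryonic fibroblasts, trypsinized and preplated to remove these feeders, and biotin-labelled cRNA was made from total RNA. The arrays formed 15 groups of 3 clones. Mouse 1 gave granulocyte-derived lines (Gra) at passages 4 and 16 and lines from skeletal muscle precursors (SMP) at passage 6. Mouse 2 gave lines from tail tip fibroblasts (TTF), B cells, T cells and granulocytes at passages 4, 10 and 16.

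The authors deposited log2 probe set values made with RMA, whose version and annotation are not stated in the labels. The values came as 2 tables from 2 array platforms, normalized separately. The first held the 33 arrays of passages 4, 6 and 16, with values from 2.261 to 14.081, and the other held the 12 arrays of passage 10, with values from 2.734 to 15.306. No contrast was fitted across the tables, so the planned contrasts of passage 10 with passages 4 and 16 were not run. Where signs, spreads, separations or correlations of passage 10 are set beside those of other passages, the platform differs as well. The labels give no date or batch, so a batch that coincides with origin or passage cannot be told apart from it. The number of arrays limits the precision.

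Gene names were taken from the probe lists of each platform. In the table of 33 arrays, 18003 of 22690 probe sets were paired with 1 symbol, 287 with several and 4400 with none. In the passage 10 table, 20393 were paired with 1 symbol, 691 with several and 1606 with none. Probe sets with 1 symbol were used, and the probe set with the highest mean stood for its gene, which left 11807 and 12394 genes. No filter on dim genes was applied. Of the 18246 probe sets listed in both, 872 carried different symbols.

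Each table was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all arrays of the table and a spread moderated across genes (lmFit, eBayes). Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as called, and all p-values of genes are two-sided adjusted values from this model unless a test is named. Moderated F-tests covered the 4 origins of mouse 2, and contrasts covered each origin against the mean of the others, each pair of origins, and the passages. The change of granulocyte-derived lines in both mice was compared as 1 contrast. Errors of log2 differences are standard errors (SE) from the model, and each group had n = 3. Clones of a comparison came from 1 mouse, except in the comparison of the mice, which had 1 mouse on each side. The p-values therefore cover the spread between clones and not between animals.

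Clone numbers were read as names of lines. Deviations from the group mean over 2000 variable genes correlated between the passages 4 and 16 of a line with a median r of 0.16, from -0.317 to 0.41, and 8 of 15 lines were their own best match. Between passages 4 and 10 the median was 0.0025 over 1945 genes. From passage 4 to 16, r was negative for all TTF lines (-0.077, -0.317 and -0.223). It was positive for all granulocyte lines and of either sign for T cell and B cell lines. Some own matches arise by chance among the clones of an origin, and their number was not tested against it. These values do not establish that a clone number names the same line. Signs per line and swaps within lines take the clone numbers as given. In the model, the clone number served as a block in an alternative fit only.

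Separation of origins was the mean of 1 minus Pearson's r between arrays of different origins, minus the mean within origins, over the 2000 most variable genes. Its p-value came from an exact two-sided permutation over 15400 splits, and the change between passages was tested by exact swaps of the passages within lines (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9). Lists of marker and pathway genes, 34 in number, were tested with camera at a preset correlation of 0.01, with the correlation estimated, and with fry, over 646 pairs of list and contrast adjusted together.

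The genes to name, the gene lists, the comparisons and the alternatives were fixed before the data were examined, except where a sentence says otherwise. Named genes were those past the test whose replicate values did not overlap between the sides, with the largest changes: 12 in each direction for granulocyte against muscle precursor lines and for passage over the origins (there with the same sign in all 12 lines), 8 for passage in mouse 1, 4 for each origin at passage 4 and 3 for passage in each origin. At passage 16 the 10 genes with the widest origin means were taken without that rule. Up to 4 called members of a list were named where the list is described. Pou5f1, Nanog, Sox2, Xist, Meg3, Rian, Col1a1, Col1a2 and Col3a1 were named in advance. Of the 120 entries of named genes, 45 had several probe sets, which moved in 1 direction in 41.

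The steps were tested on simulated data with the same groups. With 50 genes changed by 1 on the log2 scale, 36 were called in the F-test at passage 4, 49 at passage 10 and 34 at passage 16, and 50 in the pooled passage contrast. The simulated noise was independent, with 1 spread per gene for all groups of a table. In the data the spread within origins was 0.263 at passage 4 and 0.39 at passage 16. The simulation therefore cannot show that the tests at these passages were equally sensitive. Alternatives were the mean of a gene's probe sets, the dimmest 40% of genes left out, quantile normalization or cyclic loess of the tables, a trended and robust prior, only the groups of the comparison in the fit, the clone number as a block, the mean of the fibroblast list as a covariate, a minimum change of 2-fold, other genes or Spearman's rho in the separation, and each array left out. Weights per array and a fit without 1 granulocyte array were added after the data were seen.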

Results

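The data describe iPSC lines made with a secondary reprogramming system from different somatic cells of 2 mice, in 15 groups of 3 clones. The comparisons ask whether lines from tail tip fibroblasts, B cells, T cells, granulocytes and muscle precursors differ in gene expression, and what continued passage does to such differences. Correlations between an array and the others of its group averaged 0.9208 to 0.9954 in the table of passages 4, 6 and 16, and 0.9946 to 0.9976 at passage 10. The lowest value was that of the passage 16 array of granulocyte clone 3 of mouse 2.

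The core pluripotency factors were abundant in every group. Pou5f1 averaged from 10.99 ± 0.19 (SD, n = 3) in TTF lines at passage 4 to 11.54 in granulocyte lines of mouse 1 and B cell lines of mouse 2 at passage 4 (SD 0.11 and 0.10), on the log2 scale. Nanog lay between 11.15 ± 0.85 in granulocyte lines of mouse 2 at passage 16 and 12.24 ± 0.09 in B cell lines at passage 4, and Sox2 between 10.88 ± 0.20 and 11.35 ± 0.04. In the passage 10 table, which has its own scale, the group means of Pou5f1 ran from 12.98 to 13.13. At passage 4 Pou5f1 was lower in TTF lines than in the others by a log2 of -0.41 ± 0.11 (SE, adjusted p = 0.0071; -0.31 ± 0.12 and adjusted p = 0.11 without TTF clone 2), and Sox2 was higher in granulocyte lines by 0.39 ± 0.10 (adjusted p = 0.0069).

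At passage 4, 4610 of 11807 genes differed among the 4 origins of mouse 2. The pairs of origins gave 12513 calls together, from 993 between B cell and granulocyte lines to 3085 between T cell and granulocyte lines. Markers of the cell of origin were not raised as groups. Of 28 B cell genes, 0 rose in B cell lines in limma and Vpreb1, part of the surrogate light chain, was lower by a log2 of -1.26 ± 0.32 (adjusted p = 0.013; 0.099 without B cell clone 1 and 0.11 without clone 2), while the whole comparison had 2752 genes at an unadjusted p under 0.05. Of 28 T cell genes, 1 was higher in T cell lines, the T cell receptor kinase gene Zap70 (0.71 ± 0.21, adjusted p = 0.015; 0.55 ± 0.24 and 0.16 without T cell clone 2), and none adjusted over the list alone. Without TTF clone 2 or B cell clone 3 of passage 4 the T cell list had 2 higher, and without T cell clone 2 it had 1 lower. Of 32 granulocyte genes 1 was higher and 2 lower in granulocyte lines. Lyz2, which encodes lysozyme, was at 1.09 ± 0.28 (0.78 ± 0.31 and adjusted p = 0.098 without granulocyte clone 1), Cebpa at -1.08 ± 0.25 and Hp at -0.50 ± 0.17. Hp was not called without granulocyte clone 1 (adjusted p = 0.23) or 3 (0.1), TTF clone 1 (0.06), B cell clone 1 (0.062) or T cell clone 3 (0.061), and without granulocyte clone 3 of passage 16 in the fit 5 genes of the list were lower. With the fibroblast list mean as a covariate Vpreb1 was at -0.83 ± 0.36 (adjusted p = 0.24) and Zap70 at 0.46 ± 0.34 (0.59), smaller values with wider errors that were not called. Fibroblast genes were lower in TTF lines, as given with that origin. Camera gave adjusted p = 0.97 for the B cell list, 0.99 for the T cell list and 0.97 for the granulocyte list in their own lines.

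**Figure D1:**
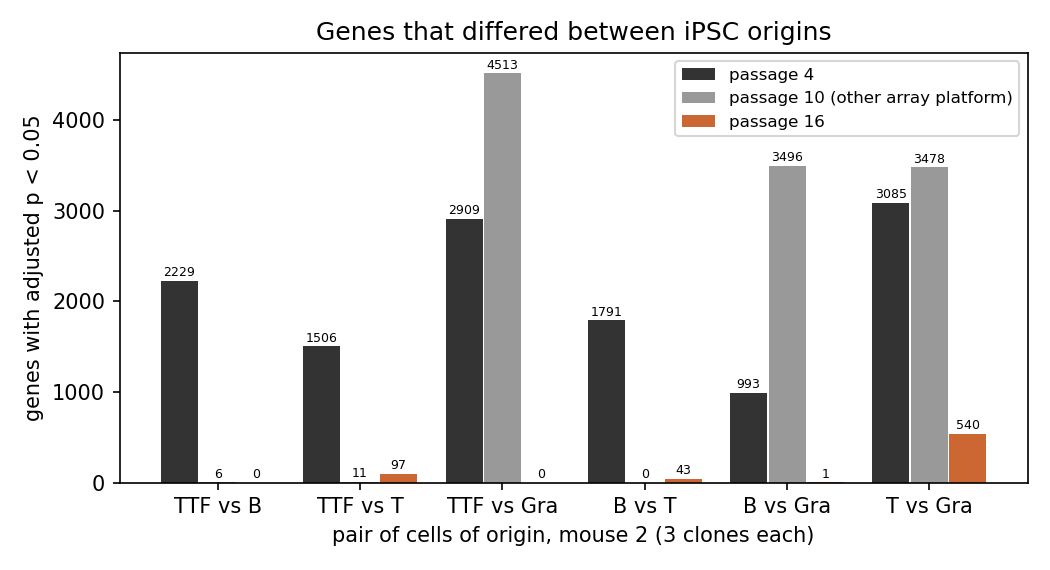
Number of genes with an adjusted p under 0.05 (vertical axis) for each pair of origins of mouse 2 (horizontal axis), with 3 clones per origin and bars for passages 4, 10 and 16. All pairs gave at least 993 genes at passage 4, the pairs with granulocyte lines gave at least 3478 at passage 10, which was measured on another platform, and at passage 16 the counts ran from 0 to 540.

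TTF lines at passage 4 had lower expression of genes for glycolysis and cholesterol synthesis. Aldoc, an aldolase of glycolysis, was 5.80-fold lower (log2 -2.54 ± 0.28, adjusted p = 6.1e-07). Ndrg1 (-1.94 ± 0.18), the mitophagy receptor gene Bnip3 (-1.65 ± 0.13) and the hexokinase gene Hk2 (-1.47 ± 0.19) were lower as well. Of 22 genes of the hypoxia and glycolysis list, 16 were lower and 0 higher. Adjusted over the list alone, 17 were lower (camera adjusted p = 1.3e-16; adjusted p = 0.2 with an estimated correlation). Cholesterol synthesis had 11 of 13 genes lower, and also 11 adjusted over the list alone, (7 without TTF clone 2 and 7 with the fibroblast list mean as a covariate), with Fdps at -2.48 ± 0.38 and the sterol demethylase gene Cyp51 at -1.42 ± 0.22 (camera adjusted p = 1.2e-08; adjusted p = 0.25 with an estimated correlation). The RNA-binding pluripotency gene Lin28a (-2.38 ± 0.38) and Lox, a collagen cross-linking enzyme gene with 2 of 3 probe sets lower (-2.49 ± 0.36), were the other most reduced genes.

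Usp17la, a deubiquitinase gene, was 7.91-fold higher in TTF lines (log2 2.98 ± 0.35), followed by Tktl1 (2.97 ± 0.32), the imprinted noncoding RNA Meg3 (2.70 ± 0.40) and the cartilage matrix gene Matn1 (2.60 ± 0.36). Rian, from the same imprinted cluster as Meg3, was higher by 1.79 ± 0.53 (adjusted p = 0.018; 1.43 ± 0.62 and 0.11 without TTF clone 3, and 1.65 ± 0.66 and 0.1 with the fibroblast list mean as a covariate), and 2 of the 3 measured genes of that cluster were called (adjusted p = 0.43 with an estimated correlation). Germline genes had 6 higher and 1 lower of 17, or 9 and 1 adjusted over the list alone and 11 and 1 without granulocyte clone 3 of passage 16 in the fit, with Tex101 at 1.91 ± 0.21, Mov10l1 at 1.87 ± 0.23, Taf7l at 1.49 ± 0.24 and Rhox5 at -1.74 ± 0.39 (adjusted p = 0.31 with an estimated correlation). Rhox5 was at -0.71 ± 0.26 and not called without TTF clone 2 (adjusted p = 0.096). Targets of p53 had 8 of 17 genes higher (5 with that covariate), including Phlda3 (1.44 ± 0.20) and the death receptor gene Fas (1.41 ± 0.28; adjusted p = 0.6 with an estimated correlation). The mean of the fibroblast list was 7.20 ± 0.11 (SD, n = 3) in these lines, against 7.21 ± 0.08, 7.91 ± 0.10 and 7.45 ± 0.06 in B cell, T cell and granulocyte lines. Of its 34 genes 10 were lower and 2 higher (adjusted p = 0.47 with an estimated correlation). In all, 1379 genes were higher and 927 lower (1262 and 1073 with quantile normalization, 1362 and 1152 with cyclic loess), and the 2306 calls became 1108 without TTF clone 2.

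B cell lines at passage 4 were higher in genes of the endoderm. The endocytic receptor gene Cubn was 7.68-fold higher (log2 2.94 ± 0.53, adjusted p = 0.00089), its adaptor gene Dab2 2.80 ± 0.62 and the transthyretin gene Ttr 1.82 ± 0.29. Of 26 endoderm genes, 11 were higher and 1 lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 3e-09; adjusted p = 0.4 with an estimated correlation). The 11 became 4 without B cell clone 2, 5 without clone 3 and 3 with the fibroblast list mean as a covariate, with list medians of 1.01, 0.49 and 0.66. The proteoglycan gene Srgn (2.95 ± 0.70) and the trypsin inhibitor gene Spink1 (2.62 ± 0.56) were higher too. The collagen gene Col6a1 (-1.91 ± 0.24), S100a4 (-1.77 ± 0.22), the p53 target Plk2 (-1.73 ± 0.21) and Cadm4 (-1.62 ± 0.20) were the lowest relative to the other origins. With the fibroblast list mean as a covariate Srgn was at 2.39 ± 0.82, Dab2 at 2.17 ± 0.72 and Spink1 at 2.03 ± 0.65, so that smaller values with wider errors ended their calls (adjusted p = 0.12, 0.1 and 0.091). The calls also ended without B cell clone 2 (0.056, 0.062 and 0.056), at 2.88 ± 0.83, 2.49 ± 0.73 and 2.29 ± 0.66. The count was 1197 genes, 449 higher and 748 lower (509 and 614 with quantile normalization, 608 and 655 with cyclic loess), and it became 1980 without granulocyte clone 3 of passage 16 in the fit, 340 with that covariate, 403 without B cell clone 1 and 348 without clone 2.

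T cell lines at passage 4 were higher in immediate early genes and in fibroblast genes. The AP-1 gene Fosb was 6.13-fold higher (log2 2.62 ± 0.24, adjusted p = 2.7e-08), with Egr2 at 2.40 ± 0.22, Jun at 1.74 ± 0.24 and Btg2 at 1.13 ± 0.21. Of 15 immediate early genes, 9 were higher, also adjusted over the list alone (camera adjusted p = 1.2e-06; adjusted p = 0.25 with an estimated correlation). Of 34 fibroblast genes, 16 were higher, or 17 adjusted over the list alone, with the matrix protein gene Mgp at 1.84 ± 0.27 and the collagen genes Col6a1 at 1.72 ± 0.24, Col3a1 at 1.56 ± 0.25 and Col1a1 at 1.18 ± 0.22 (camera adjusted p = 1.4e-06; adjusted p = 0.31 with an estimated correlation). Epithelial genes had 9 of 20 higher, among them the keratin gene Krt18 (1.31 ± 0.26) and the junction gene Tjp3 (1.74 ± 0.27; adjusted p = 0.31 with an estimated correlation). Pluripotency genes had 9 lower and 1 higher of 27, with Dppa2 at -1.80 ± 0.26, Jarid2 at -1.18 ± 0.15 and Klf2 at 0.78 ± 0.18 (adjusted p = 0.47 with an estimated correlation). Without T cell clone 2 the epithelial list had 5 higher and the pluripotency list 5 lower. The latter had 2 lower with the fibroblast list mean as a covariate. The Notch ligand gene Dll1 (2.54 ± 0.36), the myosin light chain gene Myl3 (2.81 ± 0.40) and Pdlim4 (2.77 ± 0.29) were among the highest, and Usp17la (-2.98 ± 0.35), the formin gene Diaph3 (-1.75 ± 0.18) and B3galt6 (-1.72 ± 0.23) among the lowest. With the mean of the fibroblast list, to which they belong, as a covariate Mgp was at 0.81 ± 0.39 (adjusted p = 0.28), Col6a1 at 0.71 ± 0.32 (0.23), Col3a1 at 0.69 ± 0.35 (0.33) and Col1a1 at -0.10 ± 0.21 (0.92). Klf2, from outside the list, was at 0.75 ± 0.31 (0.18), its call ended by the wider error. T cell lines gave 1456 genes higher and 758 lower (1200 and 993 with quantile normalization, 1288 and 1109 with cyclic loess). The 2214 together became 682 with the fibroblast list mean as a covariate and 1404 without T cell clone 2.

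Granulocyte lines at passage 4 were lower in immediate early genes and p53 targets and higher in pluripotency genes. Egr2 was 5.92-fold lower (log2 -2.57 ± 0.22, adjusted p = 1e-08), with Jun at -1.70 ± 0.24 and Atf3 at -1.44 ± 0.23. Of 15 immediate early genes 7 were lower and 1 higher, or 9 and 1 adjusted over the list alone (adjusted p = 0.31 with an estimated correlation). Of 17 p53 targets 10 were lower, also adjusted over the list alone, including Fas (-1.44 ± 0.28), Polk (-1.36 ± 0.21) and the cell cycle inhibitor gene Cdkn1a (-1.25 ± 0.17; adjusted p = 0.54 with an estimated correlation). Of 27 pluripotency genes 8 were higher (5 without granulocyte clone 2), including Jarid2 (1.25 ± 0.15), Dppa2 (1.08 ± 0.26) and Nr0b1 (1.07 ± 0.26; adjusted p = 0.51 with an estimated correlation). The thyrotropin-releasing hormone gene Trh (2.63 ± 0.41), the transcription factor gene Etv1 (2.63 ± 0.51), Serpinb9b (2.72 ± 0.33) and the phospholipase gene Pla2g7 (2.59 ± 0.19) were the highest. Inca1 (-2.57 ± 0.25), the repressor gene Bcl6 (-2.52 ± 0.27) and Tmem191c (-2.45 ± 0.25) were the lowest beside Egr2. There were 983 genes higher and 1745 lower (1339 and 1422 with quantile normalization, 1413 and 1632 with cyclic loess), and the 2728 calls became 1729 without granulocyte clone 1 and 1727 without clone 2.

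At passage 10 granulocyte lines stood apart from the others. All 24 measured genes of the hypoxia and glycolysis list were higher in them, with Aldoc at 1.71 ± 0.20, Ndrg1 at 1.64 ± 0.18, the oxygen sensor gene Egln3 at 1.54 ± 0.22 and the adrenomedullin gene Adm at 1.41 ± 0.08 (camera adjusted p = 9.2e-11; adjusted p = 0.47 with an estimated correlation). Fibroblast genes had 28 lower and 3 higher of 40, with Cd44 at -1.82 ± 0.23, Col5a2 at -1.69 ± 0.21, Col1a2 at -1.20 ± 0.15, Col3a1 at -1.19 ± 0.14 and Col1a1 at -0.82 ± 0.12 (adjusted p = 0.47 with an estimated correlation). Mesoderm regulators had 13 of 21 lower, with Mixl1 at -1.76 ± 0.20, Lhx1 at -1.41 ± 0.14 and Eomes at -0.89 ± 0.06 (adjusted p = 0.27 with an estimated correlation). Epithelial genes had 15 of 20 higher, including Cldn7 (1.13 ± 0.12), and p53 targets 14 of 17, including Rrm2b (0.86 ± 0.09; adjusted p = 0.46 and 0.35 with an estimated correlation). Pluripotency genes had 5 higher and 12 lower of 28 (camera adjusted p = 0.35).

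With the fibroblast list mean as a covariate none of the genes named here for granulocyte lines at passage 10 was called. The medians of the glycolysis, fibroblast, mesoderm, epithelial and p53 lists were then 0.05, 0.00, -0.33, 0.36 and 0.23, and that of the pluripotency list -0.12. Errors widened for all of them, since most of the variance of that mean lay between origins. Values shrank for Aldoc (0.42 ± 0.37, adjusted p = 0.73), Ndrg1 (0.89 ± 0.44, 0.55), Egln3 (0.02 ± 0.38, 0.99), Mixl1 (-0.42 ± 0.38, 0.73), Cldn7 (0.54 ± 0.29, 0.58) and Rrm2b (0.39 ± 0.22, 0.58). Adm was at 1.32 ± 0.23 (0.24), Lhx1 at -1.55 ± 0.39 (0.38) and Eomes at -0.73 ± 0.17 (0.38). Of the genes in the list itself, Cd44 was at -0.91 ± 0.57, Col5a2 at -0.09 ± 0.27, Col1a2 at -0.38 ± 0.31, Col3a1 at -0.26 ± 0.23 and Col1a1 at 0.07 ± 0.20 (adjusted p = 0.62 to 0.93).

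TTF lines at passage 10 were higher in 30 of 40 fibroblast genes, or 33 adjusted over the list alone. Among them were Cd44 (1.52 ± 0.23), Mgp (1.35 ± 0.19), Col1a2 (1.24 ± 0.15), Col3a1 (1.15 ± 0.14) and Col1a1 (1.04 ± 0.12; camera adjusted p = 2.5e-22, and adjusted p = 0.25 with an estimated correlation). The cell cycle inhibitor genes Cdkn2b (0.86 ± 0.12) and Cdkn2a (0.68 ± 0.11) were higher, 2 of 3 genes of their list (adjusted p = 0.35 with an estimated correlation). Xist, the RNA that silences an X chromosome, was higher by 0.90 ± 0.10 (adjusted p = 0.0013) and Meg3 by 0.82 ± 0.11. With the fibroblast list mean as a covariate none of these genes was called. Cdkn2b was at -0.14 ± 0.17 (adjusted p = 0.97) and Cdkn2a at 0.04 ± 0.25 (1), so that their difference was not seen. Xist was at 0.83 ± 0.28 (0.8) and Meg3 at 0.86 ± 0.32 (0.82), their calls ended by wider errors. Of the genes in the list, Cd44 was at 0.56 ± 0.60, Mgp at 0.00 ± 0.38, Col1a2 at 0.38 ± 0.33, Col3a1 at 0.16 ± 0.24 and Col1a1 at 0.09 ± 0.21 (adjusted p = 0.95 to 1). The fibroblast list averaged 9.27 ± 0.08 (SD, n = 3) in TTF lines, 8.88 ± 0.21 in T cell, 8.73 ± 0.09 in B cell and 8.38 ± 0.02 in granulocyte lines. In the F-test 3985 of 12394 genes differed, and the pairs gave 11504 calls, of which 4513, 3496 and 3478 were those of granulocyte lines with TTF, B cell and T cell lines. TTF and B cell lines differed in 6 genes, TTF and T cell lines in 11, and B cell and T cell lines in 0 in limma, with 1084 at an unadjusted p under 0.05. With the covariate the F-test gave 281 genes, 273 of them called without it as well, and the pairs 12 calls, 10 of them shared. The F-test gave 2463 without granulocyte clone 3.

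**Figure D2:**
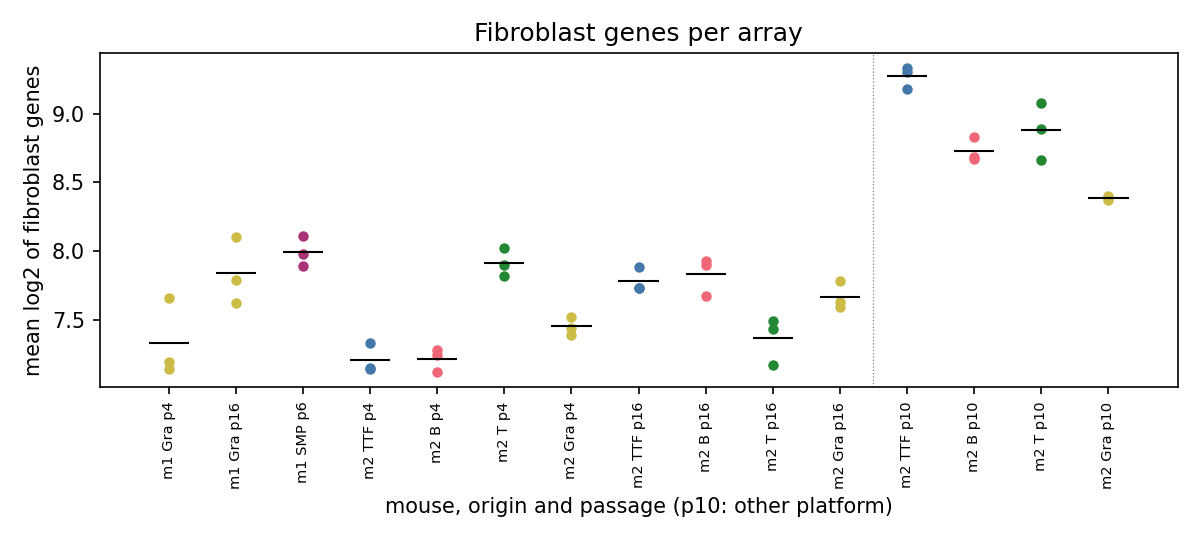
Mean log2 value of the fibroblast list (vertical axis) in each array, by mouse (m1, m2), origin and passage (horizontal axis), with a bar at the mean of 3 clones. The passage 10 groups come from another platform and run from 8.38 in granulocyte to 9.27 in TTF lines, while at passage 4 in mouse 2 T cell lines were highest at 7.91.

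By passage 16 few genes separated the origins. The F-test called 180 genes and the pairs gave 681 calls, 540 of them between T cell and granulocyte lines. T cell lines were lower in the major histocompatibility genes H2-K1 (-2.32 ± 0.33, adjusted p = 0.00023) and H2-D1 (-1.30 ± 0.17, adjusted p = 0.00013), 2 of 7 genes of antigen presentation, or 4 adjusted over the list alone and 1 with the mean of a gene's probe sets (camera adjusted p = 1.1e-05; adjusted p = 0.059 with an estimated correlation). Among the 10 genes with the widest origin means were the endoderm regulators Gata4, Gata6 and Sox17 and the endoderm gene Cubn, highest in B cell lines, at 6.95, 7.31, 7.16 and 9.12. Ctsh (7.98) and Amot (9.32) were also highest there, Meg3 (8.85) and H2-K1 (8.89) in TTF lines, Krtdap (8.01) in T cell lines and Satb1 (8.85) in granulocyte lines. Against the other origins, T cell lines gave 338 genes and granulocyte lines 303. B cell and TTF lines gave 0 genes each in limma, with 745 and 818 at an unadjusted p under 0.05. The pair of TTF and B cell lines also gave 0, with 323 unadjusted, and TTF and granulocyte lines 0, with 2518 unadjusted.

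The passage 16 counts rested on single arrays and on the fit. The limma F-test gave 0 genes with only the 12 passage 16 arrays in the fit, with 748 at an unadjusted p under 0.05. It gave from 72 without T cell clone 1 to 2031 without granulocyte clone 2. Other values were 89 without T cell clone 2, 477 without granulocyte clone 1 and 299 without its clone 3. The pairs gave 311 and 326 calls without T cell clones 1 and 2, and 2293 and 7606 without granulocyte clones 1 and 2. With only the groups compared in the fit the pairs gave 24 calls. With the fibroblast list mean as a covariate the F-test gave 79 genes and the pairs 354 calls.

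Clones of mouse 2 lay closer to their own origin than to others at passages 4 and 10. The separation was 0.121 at passage 4 (exact permutation p = 6.5e-05, the smallest that 15400 splits can give), 0.0287 at passage 10 (exact permutation p = 0.00045) and 0.0184 at passage 16 (exact permutation p = 0.049). Mean distances were 0.172 between and 0.0516 within origins at passage 4, and 0.119 and 0.1 at passage 16. The separation at passage 4 exceeded that at passage 16 by 0.102 (exact permutation p = 0.00049, the smallest that 4096 swaps within lines can give in a two-sided test). The swaps take the passages of a line as exchangeable. Since 3424 genes changed with passage over the origins, a swap can also widen the distances within an origin. The p-value therefore does not test the change of separation alone. At passage 16 its p was 0.0079 with 500 genes, 0.039 with quantile normalization, 0.048 with the mean of a gene's probe sets, 0.053 with Spearman's rho and 0.23 over all genes. It was 0.03 without granulocyte clone 3, a choice made after the data were seen. Without the clones numbered 1, 2 and 3 it was 0.68, 0.46 and 0.048, each over 105 splits.

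Of the genes that marked an origin at passage 4, the share with the same sign at passages 10 and 16 was 49.3% and 32.4% for TTF, 53.5% and 54.7% for B cell, 32.8% and 28.1% for T cell, and 19% and 32.8% for granulocyte lines. Of 2728 genes called for granulocyte lines at passage 4, 2671 were measured at passage 10, where 142 were called with the same sign and 1487 with the opposite one. For TTF lines 187 of 2251 genes were called with the same sign at passage 10 and 200 with the opposite one. Of the 8 genes that the rule names for TTF lines, Usp17la (1.03, adjusted p = 0.0013), Meg3 (0.82), Aldoc (-0.99, adjusted p = 0.011) and Fdps (-0.31, adjusted p = 0.018) had the same sign there and Lox (0.93, adjusted p = 0.005) the opposite one. The probe set of a gene was chosen on each platform separately, so it may differ between passages 4 and 10. Lox had 2 of 3 probe sets lower at passage 4. Tktl1, Matn1 and Lin28a were not called. For T cell lines 128 of 2214 genes were called with the opposite sign at passage 16 and 13 with the same. Among the 8 named for T cell lines, opposite calls were Fosb (-1.14, adjusted p = 0.0078), Dll1 (-1.53, adjusted p = 0.017) and Usp17la (1.44, adjusted p = 0.023), and the other 5 were not called. For B cell lines 3 of 1181 genes were called with the same sign at passage 10 and 0 with the opposite one. None of 1197 was called in these lines at passage 16 in limma, where 745 of all genes had an unadjusted p under 0.05.

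In mouse 1, granulocyte lines at passage 4 were compared with muscle precursor lines at passage 6, so that origin and passage differ together. Meg3 was 9.69-fold lower in granulocyte lines (log2 -3.28 ± 0.49, adjusted p = 2.6e-05), at 6.67 ± 0.32 against 9.95 ± 0.38 (SD, n = 3), and Rian was lower by -1.85 ± 0.65. Rian was not called without granulocyte clone 2 (adjusted p = 0.11) or 3 (0.14) or muscle precursor clone 1 (0.13), 2 (0.087) or 3 (0.073), nor with the fibroblast list mean as a covariate (-2.15 ± 1.01, 0.21), where the error widened. The p53 target Plk2 (-2.87 ± 0.26), the muscle genes Myl3 (-3.78 ± 0.49) and Adssl1 (-3.41 ± 0.40), the junction gene Nectin4 (-3.52 ± 0.33), Dll1 (-3.07 ± 0.44), the water channel gene Aqp3 (-3.03 ± 0.42), S100a13 (-2.94 ± 0.35), Dner (-2.89 ± 0.40), Frs3 (-2.83 ± 0.25) and Igfbp4 (-2.83 ± 0.34) were lower too. Of 17 p53 targets 11 were lower, or 13 adjusted over the list alone (camera adjusted p = 1.8e-06; adjusted p = 0.35 with an estimated correlation). Epithelial genes had 9 lower and 1 higher of 20, with Krt19 at -1.82 ± 0.31 (adjusted p = 0.25 with an estimated correlation). Muscle precursor genes had 8 lower and 3 higher of 30 in granulocyte lines (4 and 3 with the fibroblast covariate), with Sdc4 at -2.12 ± 0.47, the skeletal actin gene Acta1 at -1.93 ± 0.43 and Ncam1 at 1.74 ± 0.26 (camera adjusted p = 0.35). Fibroblast genes had 15 of 34 lower, with Col3a1 at -1.30 ± 0.30 and Col1a1 at -0.93 ± 0.27 (adjusted p = 0.33 with an estimated correlation), and their mean was 7.33 ± 0.29 against 7.99 ± 0.11 (SD, n = 3). Col1a1 was not called without granulocyte clone 2 (0.094) or 3 (0.084) or muscle precursor clone 3 (0.06). With the mean of their own list as a covariate Col3a1 was at -0.37 ± 0.40 (0.7) and Col1a1 at 0.44 ± 0.23 (0.29).

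Granulocyte lines of mouse 1 were higher in Cubn (3.75 ± 0.65), AF067061 (3.37 ± 0.53), Usp17la (3.33 ± 0.43), the neural genes Ina (2.86 ± 0.53), Zic2 (2.85 ± 0.53) and Pax6 (2.93 ± 0.46, 4 of 5 probe sets), Gm20767 (2.84 ± 0.51), and Dab2, Srgn, Tfec, Spink1 and Amot. Pluripotency genes had 10 of 27 higher (6 without granulocyte clone 1), with Dppa2 at 2.13 ± 0.31 and Gdf3 at 1.46 ± 0.29 (adjusted p = 0.43 with an estimated correlation). Endoderm genes had 8 higher and 1 lower of 26, and genes of the 2-cell-like state 6 of 9 higher, with Tcstv1 at 2.42 ± 0.46 (adjusted p = 0.71 and 0.46 with an estimated correlation). With the fibroblast list mean as a covariate Cubn was at 2.52 ± 0.95 (adjusted p = 0.097). Dab2 went from 3.59 ± 0.76 to 2.25 ± 1.13 (0.24), Srgn from 3.19 ± 0.85 to 1.98 ± 1.28 (0.41), Tfec from 3.12 ± 0.49 to 1.82 ± 0.68 (0.092), Spink1 from 3.08 ± 0.69 to 1.80 ± 1.01 (0.32) and Amot from 3.03 ± 0.50 to 1.89 ± 0.72 (0.1). Smaller values with wider errors ended these calls, and the pluripotency list then had 4 higher and the endoderm list 2. The Y-linked gene Eif2s3y was lower by -4.42 ± 1.37 (adjusted p = 0.021), and was at -3.50 ± 2.11 with the covariate (0.37). It was not called without granulocyte clone 2 (-2.76 ± 1.38, 0.2) or without muscle precursor clones 2 (0.054) or 3 (0.062). Srgn was at 2.62 ± 0.94 and not called without muscle precursor clone 2 (0.062). The 2562 calls were 1198 higher and 1364 lower, a balance that turned with quantile normalization (1275 and 1253) and cyclic loess (1420 and 1363). They became 1115 with the covariate, 4424 with only these arrays in the fit, and 1671 and 1688 without muscle precursor clones 2 and 3.

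Of the 3424 genes called for passage over the 4 origins of mouse 2, 221 changed with the same sign in all 12 lines. The lines were paired by clone number as labelled, and the genes named here were selected among these 221. Mgp fell 6.39-fold from passage 4 to 16 over the 4 origins (log2 -2.68 ± 0.17, adjusted p = 1.7e-11), in all 12 lines. The imprinted zinc finger gene Plagl1 fell by 1.49, the apoptosis gene Pmaip1 by a log2 of -1.13 ± 0.18 and the claudin gene Cldn7 by -1.33 ± 0.20. The glycogen synthase gene Gys1 rose 2.45-fold (1.29 ± 0.09), the lactate transporter gene Slc16a3 by 1.06 ± 0.06, the antiviral gene Oas1g by 1.61 ± 0.19, the X-linked homeobox gene Rhox5 by 1.60 ± 0.24 and the histone demethylase gene Kdm4b by 1.03 ± 0.10. Other genes that rose in all lines were S100a4 (1.54 ± 0.14), S100a6, Cdh11, Acss2, Phf21a, Klhl13 and Ifi202b. Those that fell were Gm9828, Rnf225, Rbbp6, Tnfrsf19, Shisa2, 2610528A11Rik, Cdo1 and Vamp2, between -1.61 and -1.06.

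**Figure D3:**
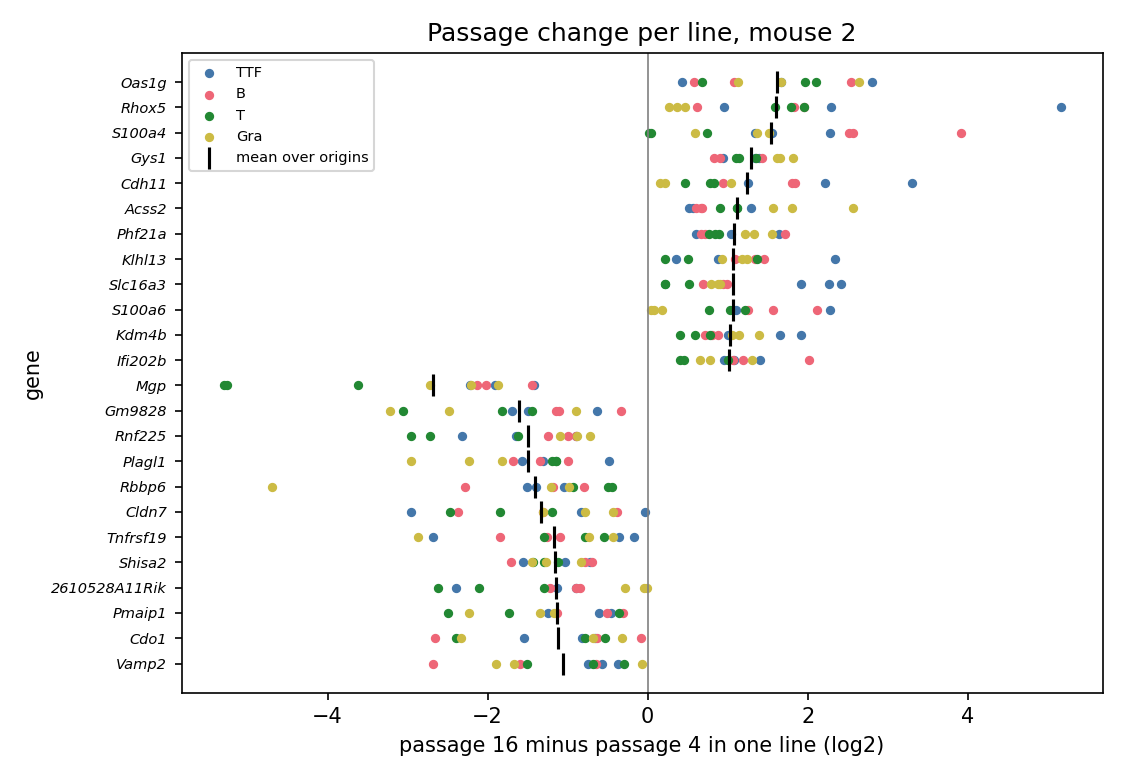
Log2 difference between passages 16 and 4 (horizontal axis) of the 24 named genes (vertical axis) in each of 12 lines of mouse 2, colored by origin, with a bar at the mean over origins. The lines were paired by clone number as labelled. The genes were selected for the same sign in all 12 lines, which 221 of the 3424 called genes had. Mgp lay between -5.30 and -1.42 and Gys1 between 0.83 and 1.81.

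Glycolysis genes rose with passage in 13 of 22 cases, or 16 adjusted over the list alone, with Ndrg1 at 1.15 ± 0.11, Egln3 at 1.05 ± 0.13 and Bnip3 at 0.83 ± 0.08 (camera adjusted p = 7.9e-07; adjusted p = 0.32 with an estimated correlation). Targets of p53 fell in 12 of 17 cases and rose in 1, with Pmaip1, Perp (-0.95 ± 0.16), Mdm2 (-0.83 ± 0.12) and Fas (-0.70 ± 0.17; camera adjusted p = 7e-06, and adjusted p = 0.4 with an estimated correlation). Of 11 DNA methylation genes 5 rose, with Dnmt3l at 0.92 ± 0.13, Dnmt3b at 0.91 ± 0.17, Dnmt3a at 0.83 ± 0.17 and Dnmt1 at 0.62 ± 0.06 (adjusted p = 0.44 with an estimated correlation). Germline genes fell in 7 of 17 cases and rose in 1, Rhox5, with Dazl at -1.42 ± 0.28 (adjusted p = 0.47 with an estimated correlation). With the fibroblast list mean as a covariate 4 of them fell and 2 rose. Fibroblast genes rose in 16 and fell in 5 of 34 cases, with Col6a3 at 1.58 ± 0.14, Col1a1 at 0.60 ± 0.14 and Mgp the largest to fall (adjusted p = 0.7 with an estimated correlation). Xist fell by -0.56 ± 0.14. Nanog had a mean of -0.35 ± 0.13 (adjusted p = 0.038) over changes of -0.33 ± 0.26 in TTF, -0.54 ± 0.26 in B cell and 0.45 ± 0.26 in T cell lines, none of them called, and a fall in granulocyte lines. The change of Nanog differed among origins (adjusted p = 0.017). It was -0.23 ± 0.09 (0.044) without granulocyte clone 3 at passage 16, and -0.34 ± 0.16 (0.16), with a wider error, with the fibroblast list mean as a covariate, where Col1a1 was at 0.15 ± 0.10 (0.31). The Nanog call ended, at adjusted p from 0.052 to 0.085, without TTF clone 2 or 3, B cell clone 2 or 3, T cell clone 1 or 3 or granulocyte clone 1 or 2 at passage 4, or TTF clone 1, B cell clone 3 or T cell clone 3 at passage 16. The 3424 calls were 1960 up and 1464 down (1725 and 1643 with quantile normalization), a balance that turned with cyclic loess (1703 and 1828). They became 1706 with the fibroblast list mean as a covariate.

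Lines from each origin also changed in their own ways. The passage 4 arrays here are those of the origin contrasts at passage 4, so these results are not independent of them. Among the genes named in both with opposite signs were Tktl1 and Matn1 in TTF lines, S100a4 and Col6a1 in B cell lines and Pla2g7 in granulocyte lines. In TTF lines 16 of 22 glycolysis genes rose, with Ndrg1 at 2.55 ± 0.22 and Aldoc at 2.41 ± 0.34 (camera adjusted p = 1.7e-21; adjusted p = 0.09 with an estimated correlation), as did 9 of 13 cholesterol genes (5 without TTF clone 2 at passage 4, 3 with the fibroblast covariate), with Fdps at 2.23 ± 0.47 (adjusted p = 0.25 with an estimated correlation). Sfmbt2 (2.94 ± 0.35), Rhox5 (2.80 ± 0.48) and Enpp3 (2.57 ± 0.45, 3 of 4 probe sets) rose most, and Tktl1 (-2.99 ± 0.39), 1300017J02Rik (-2.72 ± 0.29) and Matn1 (-2.60 ± 0.45) fell most. The mean of the fibroblast list went from 7.20 to 7.78. Rhox5 rose by 1.77 ± 0.31 without TTF clone 2 at passage 4. Rhox5 and Enpp3 lost their calls with only these arrays in the fit (adjusted p = 0.09 and 0.054). In B cell lines S100a4 rose 8.03-fold (3.01 ± 0.28) with the collagen genes Col6a1 (2.67 ± 0.29) and Col6a3 (2.48 ± 0.28). Of 34 fibroblast genes 13 rose and 1 fell (8 rose without B cell clone 2 at passage 4 or clone 3 at passage 16; adjusted p = 0.31 with an estimated correlation), the list mean going from 7.21 to 7.83. The imprinted gene Snurf fell by -2.92 ± 0.56, Rabac1 from 9.03 ± 0.28 to 7.03 ± 0.56 (SD, n = 3) and Six4 by -1.99 ± 0.48. With the fibroblast covariate they changed by -3.04 ± 0.83, -1.83 ± 0.64 and -1.62 ± 0.71, and their calls ended (adjusted p = 0.15, 0.27 and 0.42), mostly through wider errors. Six4 changed by -1.60 ± 0.52 and was not called without B cell clone 3 at passage 16 (0.093).

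In T cell lines the immediate early genes fell in 8 of 15 cases, with Egr2 at -2.68 ± 0.27 and Fosb at -2.49 ± 0.29 (camera adjusted p = 9.4e-07; adjusted p = 0.25 with an estimated correlation). The fibroblast genes fell in 12 and rose in 1 of 34 cases, their mean going from 7.91 to 7.36 (7 fell without T cell clone 2 at passage 4 and 6 without it at passage 16; adjusted p = 0.47 with an estimated correlation). Mgp fell 26.5-fold (-4.73 ± 0.33), Dpp7 by -3.23 ± 0.47 and Tmem106b by -2.98 ± 0.35, and Usp17la (3.46 ± 0.43), AF067061 (3.21 ± 0.53) and Serpinb9b (2.35 ± 0.40) rose. In granulocyte lines the median of all genes changed by 0.21 (0.05 with quantile normalization and 0.01 with cyclic loess), which the values below include. There 6 of 7 antigen presentation genes rose, the immunoproteasome genes Psmb8 by 1.72 ± 0.31 and Psmb9 by 1.37 ± 0.19 and H2-D1 by 1.21 ± 0.21 (camera adjusted p = 0.0081; adjusted p = 0.25 with an estimated correlation), and 5 did so without the array of clone 3 at passage 16, where Psmb8 rose by 1.03 ± 0.17, Psmb9 by 1.34 ± 0.21 and H2-D1 by 1.25 ± 0.23. Pluripotency genes fell in 13 of 27 cases, with Nr0b1 at -1.72 ± 0.32, Zfp42 at -1.13 ± 0.28, Tfcp2l1 at -1.04 ± 0.23 and Nanog going from 12.16 ± 0.16 to 11.15 ± 0.85 (SD, n = 3, adjusted p = 0.0043; camera adjusted p = 1.2e-06; adjusted p = 0.33 with an estimated correlation). Without that array 6 fell, with Nr0b1 at -1.09 ± 0.23, Zfp42 at -0.56 ± 0.19 (adjusted p = 0.041), Tfcp2l1 at -0.72 ± 0.21 and Nanog at -0.51 ± 0.19 (adjusted p = 0.055). The carbonic anhydrase gene Car4 (2.76 ± 0.61), Selenbp1 (2.64 ± 0.44) and Gdpd5 (2.61 ± 0.39) rose most, and Dazl (-3.29 ± 0.57), Pla2g7 (-3.04 ± 0.23) and the growth factor gene Bmp4 (-2.98 ± 0.50) fell most. Selenbp1 rose by 1.69 ± 0.29 without clone 3 at passage 16. Selenbp1 and Gdpd5 were not called with only these arrays in the fit (adjusted p = 0.091 and 0.054).

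**Figure D4:**
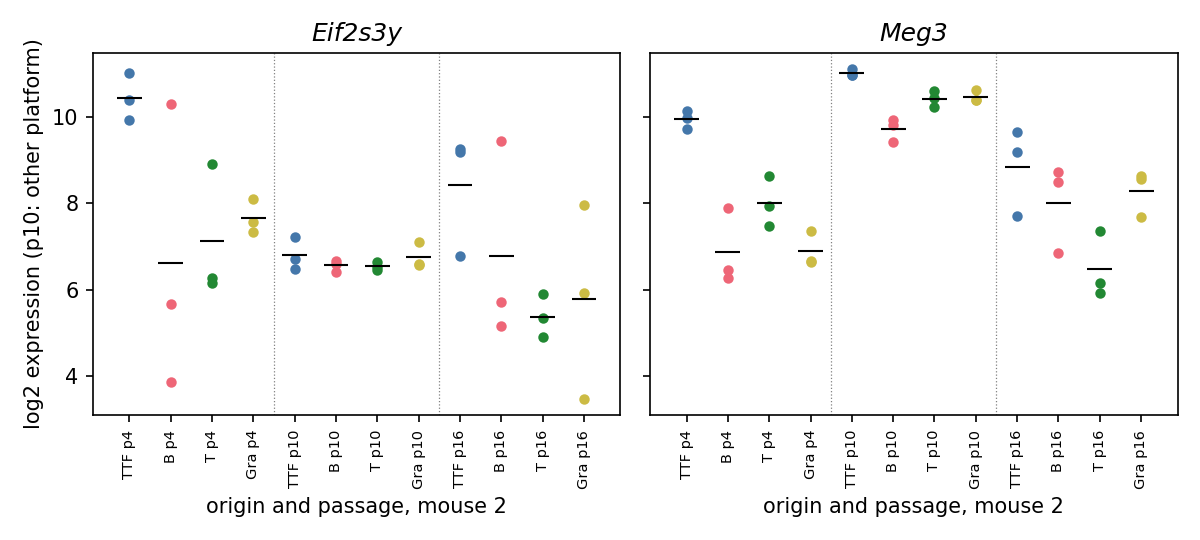
Log2 values (vertical axis) of the Y-linked gene Eif2s3y and the imprinted RNA Meg3 in each clone of mouse 2, by origin and passage (horizontal axis), with a bar at the mean of 3 clones. Clones of an origin spanned up to 6.45 for Eif2s3y at passage 4 and up to 0.74 at passage 10, which was measured on another platform.

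Counts of genes that changed with passage were 1439 in TTF, 945 in B cell, 2113 in T cell and 4249 in granulocyte lines. In granulocyte lines the count became 533 with only these arrays in the fit, 2370 without clone 3 at passage 16, and 2644 and 2784 without clones 1 and 2 at passage 4. In TTF lines it became 934 without clone 2 at passage 4, 849 without clone 2 at passage 16, 557 with only these arrays in the fit and 409 with the fibroblast covariate. In B cell lines it became 1712 without granulocyte clone 3 of passage 16 in the fit, 29 with that covariate, 618 with the line as a block, 530 and 416 without clones 1 and 2 at passage 4, and 356 without clone 3 at passage 16. In T cell lines it became 1156 with the covariate. The passage change differed among the origins in 3876 genes, a test in which the origin differences at passage 4 take part.

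In mouse 1, granulocyte lines showed a smaller set of passage changes. S100a4 rose 9.09-fold (log2 3.18 ± 0.28, adjusted p = 7.1e-08), and the collagen genes Col6a3 (2.37 ± 0.28) and Col6a1 (2.36 ± 0.29) and the interferon-inducible gene Ifi202b (1.80 ± 0.24) rose with it. The protease gene Prss12 (from 6.33 ± 0.87 to 4.32 ± 0.32, SD, n = 3), Mgp (-1.82 ± 0.33), Egr2 (-1.76 ± 0.27) and Phlda1 (-1.71 ± 0.30) fell. Of 34 fibroblast genes 8 rose and 1 fell, or 13 and 2 adjusted over the list alone, and 3 rose without clone 2 or 3 at passage 4 or clone 1 at passage 16. Their mean went from 7.33 to 7.84 (camera adjusted p = 1.1e-07; adjusted p = 0.27 with an estimated correlation). With their mean as a covariate Ifi202b was at 1.25 ± 0.27 (adjusted p = 0.059), Prss12 at -1.57 ± 0.47 (0.25), Egr2 at -1.47 ± 0.35 (0.076) and Phlda1 at -1.42 ± 0.40 (0.2), and smaller values with wider errors ended these calls. Prl2c2, Dll1, Rab3il1 and Igfbp4 (1.62 to 1.87) and Ttr, Lhpp, Pax6 (2 of 5 probe sets) and Dpp4 (-1.84 to -1.74) were also called and each lost its call without at least 1 of the 6 arrays and with the covariate. Pax6 lost its call without each of them in turn (adjusted p = 0.091 to 0.18). It was at -0.50 (0.18) with the mean of its probe sets, -1.84 (0.087) with quantile normalization and -1.88 (0.058) with cyclic loess. The 135 calls became 314 without granulocyte clone 3 of mouse 2 at passage 16 in the fit, 15 with the covariate, 76 with the line as a block, 332 with only these arrays in the fit, 83 and 48 without clones 1 and 2 at passage 4, and 58, 82 and 64 without clones 1, 2 and 3 at passage 16. Of these genes, 83 were called in granulocyte lines of mouse 2 as well, 73 of them with the same sign, where independent calls would give 26.9. The change itself differed between the mice, with 1 animal on each side, in 429 genes (102 with only these groups in the fit, and 147 to 1849 without single arrays).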

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

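The tests of explanations in this part and the bounds for the counts over other groupings were written, and the groupings without granulocyte clone 3 run, after the results were seen, while the tests of differences in passage change were planned.

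The change from passage 4 to 16 differed among the 4 origins of mouse 2 in 3876 genes, by the test of the difference itself. In 100 regroupings of the 12 lines the highest other count was 2518, and 1 grouping, the real one, gave as many, so chance was excluded. The F-test at passage 4 with the covariate below happens to give the same number, and the sets share 2991 genes. Granulocyte lines of both mice changed differently with passage in 429 genes, again by the test of the difference, with 1 animal on each side. The number was 102 with only these groups in the fit, 237 with the fibroblast list mean as a covariate and 259 with the line as a block. The 10 splits of the 6 lines are too few for a share under 0.05, with 0 as the highest other count. That count moved with single arrays: in mouse 1 it was 199 and 185 without clones 2 and 3 at passage 4 and 172 and 147 without clones 1 and 2 at passage 16, and in mouse 2 it was 193 and 155 without clones 1 and 2 at passage 4 and 837 and 1849 without clones 1 and 2 at passage 16.

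Origin at passage 4 and the RNA of fibroblasts went together, since 94.2% of the variance of the fibroblast list mean over the 12 arrays lay between origins. These genes may come from feeder cells left after preplating or from the lines themselves. With the list mean as a covariate, 3876 genes differed among origins at passage 4, 3781 of them also called without it. That fit cannot decide whether fibroblast RNA was the whole cause of the 4610, since its slope rests on the small spread within origins. TTF and B cell lines had list means of 7.20 and 7.21 and differed in 2229 genes, which argues against fibroblast RNA as the whole cause for that pair. At passage 10, 91.1% of the variance of the list mean lay between origins. There 281 genes were called with it as a covariate, 273 of them among the 3985 called without. Glycolysis genes were higher in granulocyte lines by a median of 0.63 while the pluripotency list had a median of -0.10. A smaller share of fibroblast RNA alone would not give this, though the glycolysis median was 0.05 with the covariate. Fibroblast genes were not raised in TTF lines at passage 4, where the list had a median of -0.33. That median is relative to other lines, whose share of feeder RNA may differ. It therefore cannot exclude expression kept from the tail tip fibroblasts as a source of the high fibroblast genes at passage 10. Feeder carry-over and differentiation stayed open too.

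The passage 16 array of granulocyte clone 3 of mouse 2 correlated with the other arrays, over genes, at a mean r of 0.904, where the others had 0.962 to 0.987. The deviation from the mean of clones 1 and 2 had a median of 0.63 in the dimmest 10% of genes and of -0.36 in the brightest 10%, a difference of 0.99, against 0.13 between those clones, which is consistent with a weak signal. A loss of pluripotency in this culture over the list as a whole was argued against. The pluripotency list lay at a median of -0.41 and genes of the same level at -0.39, a gap of -0.02. A loss limited to some genes of the list was not tested. An array of another group under this name cannot be told apart, since its highest r with any array was 0.94 and a compressed signal lowers r with every array. Nanog was at -1.47, Pou5f1 at -0.14 and the integrin gene Itgb1 at -3.26, and why Itgb1 was so low stayed open.

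Clones of an origin lay closer together at passage 10 than at the other passages, with a spread within origins of 0.142 against 0.263 at passage 4 and 0.39 at passage 16, over 11485 genes (0.279 without granulocyte clone 3 of passage 16). Between origins it was 0.162 at passage 10, 0.342 at passage 4 and 0.116 at passage 16. Both shrank from passage 4 to 10 by like factors, with a ratio of 0.88. The SD over genes in an array was 2.771 to 2.823 at passage 10 and 2.332 to 2.679 in the other table, so the scale as a whole was not narrower. Like factors alone do not single out a cause, and the other platform or its normalization may account for the closeness. Clone numbers exchanged within an origin at passage 10 would leave its spread as it is, so they cannot account for the closeness. Cultures not kept as separate clones cannot be told apart from the platform. The genes that marked clones at passages 4 and 16 had a spread ratio of 0.707 and a median r of 0.052 between passages 4 and 10. They numbered 37, where 100 shuffles of the clone numbers gave a median of 40, so they cannot decide this. The design gives no biological explanation of this closeness that was tested.

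Other groupings of the same arrays were fitted for the remaining counts. Chance was excluded for the F-test at passage 4 (4610, highest other 1429), the pairs at passage 4 (12513, 3771), TTF (2306, 1009), T cell (2214, 1983) and granulocyte lines (2728, 861), each with 1 of 100 groupings as large. For T cell lines, and for the pairs at passage 10 below, the highest other count lay near the real one, so the exclusion is weaker there. For B cell lines (1197) 3 of 99 groupings were as large, a share under 0.05, but the highest, 1597, was above the real count. Chance was therefore not clearly excluded for that count. At passage 10 it was excluded for the F-test (3985, highest other 3169) and the pairs (11504, 10431), with 1 of 100 as large. At passage 16 chance could not be excluded: 14 of 100 groupings gave at least the 180 genes of the F-test, the highest 3134, and 19 gave at least the 681 calls of the pairs, the highest 10119. Groupings that call many times the real number point to a structure of the passage 16 arrays. Without granulocyte clone 3 the highest were 472 against a real 299 for the F-test (5 of 100 as large) and 2220 against 940 for the pairs (10 of 100), so the highest counts were lower without that array, and chance could not be excluded there either. For passage over the origins chance was excluded (3424, highest other 812 with passages exchanged within origins and 2822 within lines, 1 of 100 as large in both). The 10 splits of 3 against 3 arrays were too few for a share under 0.05, with the real and highest other counts at 2562 and 0 for granulocyte against muscle precursor lines, 135 and 0 for passage in mouse 1, and 1439 and 4, 945 and 15, 2113 and 1, and 4249 and 56 for passage in TTF, B cell, T cell and granulocyte lines.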

How the results depend on the processing

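Weights per array and the fit without granulocyte clone 3 of passage 16 were chosen after the data were seen, and the cause of each changed value below was not tested. The main counts held within 1.5-fold with the mean of a gene's probe sets (24 results), quantile normalization (23), cyclic loess (19) and a trended and robust prior (19). Counts of members within single lists were not among these results. The separation kept its side of the threshold with 500 genes (4). The passage 10 contrasts with passages 4 and 16 were not run, since the tables differ in platform and normalization. Where a group was left with 2 arrays, they were assumed to vary like the other groups. Arrays give no read depth. Leaving out the dimmest 40% of genes took the list calls from 149 of 646 tests to 86 of 566, and the other 19 results tried with it held within 1.5-fold. With an estimated correlation they were 0 in camera (149 with fry).

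With the fibroblast list mean as a covariate the counts were 340 (B cell lines, passage 4), 682 (T cell), 281 (F-test, passage 10), 79 (F-test, passage 16), 1115 (granulocyte against muscle precursor), 15 (passage, mouse 1), 1706 (passage over origins), 409, 29 and 1156 (passage in TTF, B cell and T cell lines), 237 (passage change between mice), and 7914, 12 and 354 (pairs at passages 4, 10 and 16). A change of 2-fold as well gave 2200, 484, 197, 437 and 594 (F-test, TTF, B cell, T cell and granulocyte lines, passage 4), 326 and 114 (F-tests, passages 10 and 16), 965 (muscle precursor), 72 (passage, mouse 1), 72 (over origins), 521, 250, 692 and 1341 (TTF, B cell, T cell and granulocyte passage), and 4453, 597 and 303 (pairs). With only the groups compared in the fit there were 0 in the limma F-test at passage 16 (748 unadjusted), 4424 (muscle precursor), 332 (passage, mouse 1), 557 and 533 (TTF and granulocyte passage), 102 (between mice) and 24 (pairs, passage 16). With the line as a block there were 76 (passage, mouse 1), 618 (B cell passage) and 259 (between mice).

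Weights per array, whose estimation stopped before converging, gave 7295, 3923, 3779 and 5394 (F-test, B cell, T cell and granulocyte lines, passage 4), 5315 (F-test, passage 16), 6430 (muscle precursor), 3208 (passage, mouse 1), 3604, 4151 and 7388 (B cell, T cell and granulocyte passage), 7214 (difference among origins), 5372 (between mice), and 22582 and 10989 (pairs, passages 4 and 16). Without granulocyte clone 3 of passage 16 there were 6046, 3342, 1980, 3045 and 3697 (F-test, TTF, B cell, T cell and granulocyte lines, passage 4), 3382 (muscle precursor), 299 (F-test, passage 16), 314 (passage, mouse 1), 2157, 1712, 3154 and 2370 (TTF, B cell, T cell and granulocyte passage) and 17786 (pairs, passage 4), several outside the ranges below. The separation at passage 16 was 0.00228 over all genes (p = 0.23) and 0.0188 with Spearman's rho (p = 0.053), both by exact permutation.

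Leaving out each array of the groups compared in turn gave 3997 to 4582 (F-test, passage 4), 1108 to 2333, 348 to 1259, 1404 to 2235 and 1727 to 2751 (TTF, B cell, T cell and granulocyte lines), 2463 to 3870 and 72 to 2031 (F-tests, passages 10 and 16), 1671 to 2412 (muscle precursor), 48 to 119 (passage, mouse 1), 2925 to 4539 (over origins), 849 to 1443, 356 to 849, 1583 to 1821 and 2370 to 6106 (passage by origin), 3216 to 5177 (difference among origins), 147 to 1849 (between mice), and 10158 to 12255, 7987 to 11505 and 311 to 7606 (pairs). Leaving out each clone number gave separations of 0.103 to 0.134, 0.0286 to 0.029 and 0.0106 to 0.0195 at the 3 passages, and a change of 0.0879 to 0.114. Of the 120 named entries, 25 lost their call with the covariate, 5 with only the groups compared, 3 with quantile normalization, 2 with the block, 1 with loess and 1 with the mean of probe sets. None of these entries reversed under those settings. Without single arrays 33 of 1344 fits lost the call and none reversed. The entries had been selected for large changes and for replicate values that did not overlap between the sides. For passage over the origins they were selected for the same sign in all lines. Leaving out a single array could therefore hardly reverse them, and the lack of reversals there is no test of their direction.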

Other observations

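The list tests in this part were planned, and the lists described and the genes shown by clone were picked after their values were seen.

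Of the endoderm genes that the rule names for B cell lines at passage 4, Cubn was at 0.92 at passage 10 (adjusted p = 0.031) and Dab2 at 0.61 (0.22). As a list, endoderm genes had a raised median in B cell lines at passage 16. None of the 26 was called over all genes in limma, where the comparison had 745 genes at an unadjusted p under 0.05, and 19 were higher adjusted over the list alone. Without B cell clone 2 of passage 16, 8 were called. Their median was 0.92 (camera adjusted p = 4.3e-28; adjusted p = 0.2 with an estimated correlation). Fibroblast genes of T cell lines had a median of -0.34 at passage 16, with 7 of 34 lower, or 14 adjusted over the list alone, 4 without T cell clone 1, 1 without clone 2 and 11 without granulocyte clone 3 (adjusted p = 0.31 with an estimated correlation). In granulocyte lines at passage 4, 7 of 19 neural genes were higher, with a median of 0.15 (adjusted p = 0.47 with an estimated correlation). Heat shock genes fell with passage over the origins in 4 of 10 cases (adjusted p = 0.31 with an estimated correlation). The number was 2 with the fibroblast list mean as a covariate. Leaving out TTF clone 3, B cell clone 2 or granulocyte clone 1 of passage 4 also gave 2. So did leaving out TTF clone 3, B cell clone 1 or T cell clone 3 of passage 16.

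Single genes differed strongly between clones of an origin. The Y-linked gene Eif2s3y was at 5.66, 10.31 and 3.85 in the B cell clones at passage 4, and at 5.71, 9.46 and 5.16 at passage 16. In granulocyte lines of mouse 1 it was at 8.02, 2.96 and 7.86 at passage 4. The imprinted RNA Rian spanned 3.47 between B cell clones at passage 4, and Meg3 1.95 between TTF clones at passage 16. Xist lay between 5.86 and 7.49 in mouse 2 at passages 4 and 16.

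Of 34 lists, 6 were not called in any of 19 contrasts: T cell markers (lowest adjusted p = 0.072), Y-linked genes (0.094), muscle precursor markers (0.17), markers shared by blood cells (0.12), polycomb genes (0.078) and trophectoderm genes (0.055), all by camera.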
